A study of Mus musculus with 12 samples.

How the data were processed

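RNA from whole stomach and colon of 16 week old Spdef wild type, heterozygous and knockout mice was measured on 12 Affymetrix mouse expression arrays, with 2 arrays in each of 6 groups. The deposited values are a linear intensity per probe set, between 0.16 and 32077, with a trimmed mean between 500.07 and 500.09 on every array. The authors' notes name MAS5 for 9 arrays and RMA for 3 (stomach KO 1, stomach KO 2 and colon WT 1), with no version. The columns were checked for a difference between these notes and looked alike on pooled values. The share of values below 16 was 15.4% against 14.8%, and the median of the array medians was 139 against 135. Singly, colon WT 1 had the highest median, at 159 against 123 to 147 for the other arrays. In stomach the RMA note falls on the KO arrays alone, so a difference in processing there could not be told apart from genotype. No log scale was present in any column.

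The table held 22716 probe sets, of which 90 controls were left out. Of the remaining 22626, 18003 had 1 gene, 287 had several genes and 4336 had none. Current symbols were taken through the gene identifiers for 17977 probe sets and kept as given for 26. Each of 11807 genes was represented by the probe set with the highest mean, with 4150 genes having several to choose from, and that choice was held in every alternative that tested 1 probe set per gene. No genome build comes with the arrays, so no coordinates are given; chromosome and gene order were read from the RefSeq annotation of GRCm38.p6.

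Values were taken as log2(intensity + 16). Quantile normalization over the 12 arrays was applied because the 25th and 50th percentiles of the colon arrays spread over 0.28 and 0.33, beyond the limit of 0.25 set before the data were examined. A gene was tested in a tissue when it reached the 40th percentile of its array (6.53, an intensity of 76.5) in at least 2 of the 6 arrays. Where 1 group mean lay below that level, a difference named in the text is given as a lower bound against it. Array number, not depth, limits the precision.

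A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, 6 residual degrees of freedom and 3.29 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of the tissue, at a threshold of 0.05. The comparisons were KO, HET and WT within each tissue, the KO effect between tissues, and WT colon against WT stomach. Calls shared between tissues were tested with Fisher's exact test. A set of 28 gene lists of cell types and processes, with 454 entries of which 381 were matched, was fixed before the data were examined. Lists of at least 3 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Differences of HET and KO from shared WT arrays were compared with simulated unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

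Named genes were fixed by a rule before the data were examined: Spdef; the genes past the threshold whose arrays did not overlap, or the 10 with the smallest p where fewer than 10 passed; and up to 4 members of each list with the largest differences. The alternatives were the deposited values without quantile normalization, offsets of 1 and 64, no filter, a filter at the array median and no intensity trend. Further ones were each tissue fitted alone, every probe set tested, the replicate number as a block and leaving out each array in turn. Leaving out the KO array of each tissue with low Xist was added after the data were seen. The pipeline was tested on simulated data with 200 changed genes.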

Results

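Transcript levels were measured in whole stomach and colon tissue of 16 week old mice that were wild type (WT), heterozygous (HET) or knockout (KO) for Spdef, an ETS family transcription factor known from goblet cells and other mucus-producing cells. There were 12 samples, each on an Affymetrix mouse expression array, a chip on which each transcript is read by a set of short probes. They formed 6 groups, 1 for each genotype in each tissue, with 2 samples per group. The labels give C57BL/6 as the strain of all samples and state neither the sex of the animals nor whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples. The deposited values were linear intensities, and each array had a trimmed mean close to 500.1. Arrays carry no read depth, and their number limits the precision. All levels below are log2(intensity + 16) after quantile normalization, so fold changes of dim genes are understated, and a difference marked "at least" is taken against the filter level of 6.53 because 1 group mean lay below it. After a filter on dim genes, 7858 genes were tested in stomach and 7913 in colon.

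Spdef itself, on chromosome 17, was read by a single probe set on every array. In stomach it lay at 9.19 and 8.96 in the WT arrays, at 9.06 and 8.94 in the HET arrays and at 8.86 and 8.63 in the KO arrays. The KO mean was lower than the WT mean by a log2 difference of -0.33 (SE 0.55), which was not past the threshold in limma (adjusted p = 0.9995). In colon it lay at 10.97 and 8.74 in the WT arrays, at 10.27 and 9.81 in the HET arrays and at 9.08 and 9.25 in the KO arrays. The array labelled colon WT 2 therefore read lower than both colon KO arrays. The KO minus WT difference in colon was -0.69 (SE 0.55, adjusted p = 0.619) over all arrays and -1.80 (SE 0.23, adjusted p = 0.0113) without that array, and without colon WT 1 it turned to 0.42. Where this probe set lies relative to the deleted part of the gene is not known, so a signal in the KO arrays neither supports nor contradicts their labels.

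**Figure D1:**
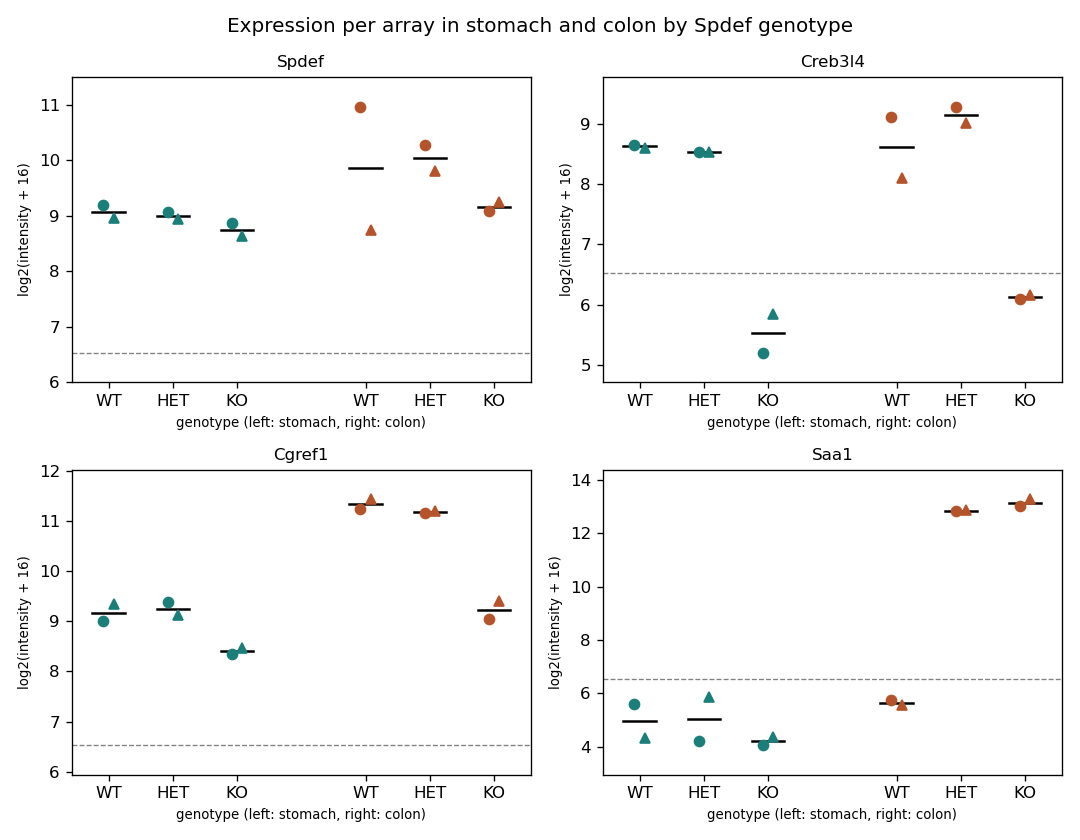
Levels of Spdef, Creb3l4, Cgref1 and Saa1 on the log2(intensity + 16) scale in each array, by genotype within stomach (teal) and colon (orange). Circles are replicate 1, triangles replicate 2, bars the mean of the 2 arrays, and the dashed line is the 40th percentile of an array, at 6.53. Creb3l4 lies below that line in the 4 KO arrays and above it in the other 8, and Saa1 lies above it in the colon HET and KO arrays alone.

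The tissues were told apart by the genes of their cell types. Of the 8393 genes tested between WT colon and WT stomach, 919 were higher in colon and 1374 were higher in stomach. Genes of acid-secreting parietal cells were lower in colon in 8 of 9 cases, including the proton pump subunits Atp4a (by at least 7.32) and Atp4b (at least 7.70), and all 6 genes of enzyme-secreting chief cells were lower, including Pgc (at least 7.74), Cblif (at least 7.38) and Pga5 (at least 6.12). Genes of the gastric surface mucous cell were lower in 10 of 11 cases, among them Gkn1 (at least 7.44) and the gastric mucin Muc5ac (at least 7.24). Of the absorptive colonocyte genes, 14 of 16 were higher in colon, including Guca2a (at least 7.39) and Muc3 (at least 7.22), and of the goblet cell genes 19 of 28 were higher and 3 lower, with Zg16 higher by at least 7.74 and Tff3 at 7.20. These 4 lists of parietal, chief, surface mucous and absorptive cells also passed with an estimated correlation between their genes (adjusted p from 0.00359 to 0.0125), as did the list of antimicrobial and epithelial defence (adjusted p = 0.0323), and the goblet list did not (adjusted p = 0.405 with an estimated correlation). Without colon WT 2 the numbers were 984 higher and 1213 lower. The sum of 2293 genes dropped to 1105 without stomach WT 1, 1379 without stomach WT 2 and 1517 with the replicate block, and was 2943 without colon WT 1.

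A single colon array stood apart from the rest. The mean correlation across genes of the array labelled colon WT 2 with the other colon arrays was 0.888, against 0.931 to 0.956 for the others. In it the lipid-handling genes Apoa1 (14.32) and Mttp (12.07), the bile acid binding protein Fabp6 (14.42), the bile acid induced hormone Fgf15 (9.78) and the Paneth cell defensin Defa31 (13.87) were high, while the colonic genes Car1 (6.65) and Aqp8 (5.54) were low. In the other 5 colon arrays Fabp6 was at most 8.73 and Car1 was at least 13.50. Hoxa10 lay at 4.81 in the array labelled colon WT 2, against 7.74 to 9.51 in the other colon arrays and 5.02 to 5.66 in stomach. The Fabp6 value of 8.73 was that of colon WT 1, against 5.84 to 6.61 in the HET and KO arrays. Defa31 (8.10 against 4.14 to 5.13) and Apoa1 were also higher in colon WT 1 than in those arrays. Mttp (5.19) and Fgf15 (4.26) in colon WT 1 did not exceed the HET and KO arrays. The genes in this paragraph were chosen after their values were seen. The colon counts are given with and without the array labelled colon WT 2, and those without it have colon WT 1 as the only WT array.

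The first comparison asked which genes changed in the stomach when Spdef was lost. Creb3l4, a membrane-bound transcription factor of the endoplasmic reticulum (ER), was lower in both KO arrays (5.52 ± 0.45, SD, n = 2) than in the WT arrays (8.63 ± 0.04, SD, n = 2). It fell by 3.11 on the log2 scale (SE 0.32, limma adjusted p = 0.0284). As both KO arrays read below the 40th percentile of all probe sets, this is at least a 4.29-fold decrease. No other gene passed, with 0 higher and 1 lower of 7858 tested, and 280 genes had an unadjusted p under 0.05 against 393 by chance. The spread behind this and the other stomach comparisons was estimated over all 12 arrays, the array labelled colon WT 2 included. The low count therefore does not show that stomach was unchanged. Both stomach KO arrays, and no other stomach array, carry the processing note RMA. The genes with the next smallest p-values did not pass. They were Krtdap (at least 19.7-fold lower) and Mt4 (at least 4.57-fold lower) of cornifying squamous epithelium, the chemokine Ccl20, whose WT and KO means both lay below the filter level, the plasma protein Serpina1b (at least 4.68-fold lower, and 3.07-fold without WT 1) and the urinary protein Mup3 (at least 7.74-fold lower, 2.43-fold without WT 1 and 24.6-fold without WT 2), both made mainly by liver, then Uri1 (-1.20), Pop4 (-0.96), Uevld (higher by at least 1.08) and Arrdc4 (1.09), with adjusted p-values from 0.407 to 0.568. A second Arrdc4 probe set showed only 0.20. Creb3l4 was lower in KO in each of 22 alternatives and lost its call in 12 of them (adjusted p from 0.00113 to 0.276), among them the deposited values without normalization between arrays, an offset of 64, the replicate block, and leaving out any stomach WT or KO array or any colon HET or KO array. The count rose to 7 when stomach was fitted alone (2 higher, 5 lower, with Dmbt1 higher by 2.21 and Adipoq lower at -1.82), to 9 without HET 1 and to 9 without HET 2, and to 3 without colon WT 1 and without colon WT 2.

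Among the gene lists fixed in advance, 2 of 25 passed in stomach, both lower in KO. All 9 tested genes of the squamous epithelium that lines the forestomach had negative differences, with a median of -2.51 (adjusted p = 7.6e-10), and of -1.94 with group means below the filter level raised to it. The median was -3.99 without WT 1 and -3.89 without HET 1. They were led by Krtdap, Sprr3 (lower by at least 2.69), Krt4 (at least 1.97) and Krt13 (at least 2.96). Of these 9 genes none passed over all genes and 4 passed when adjusted over the list alone. The list's mean level was 8.22 and 9.35 in the WT arrays, 10.44 and 7.23 in the HET arrays and 5.90 and 6.07 in the KO arrays, where 7 of the 9 genes lay below the filter level. The 4 adipose genes had a median of -0.66 (adjusted p = 0.0371), with Adipoq at -1.82, Fabp4 at -0.78, Retn lower by at least 0.43 (0.12 without WT 2) and Plin4 at -0.46, and the call was lost without KO 1 (adjusted p = 0.182) and without WT 2 (adjusted p = 0.111). Neither call held with an estimated correlation (adjusted p = 0.530 for the squamous list and 0.930 for the adipose list with an estimated correlation), although without HET 1, where 7 squamous genes were tested, the squamous list passed with it (adjusted p = 0.0262 with an estimated correlation).

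The lists of mucus-producing cells did not pass in stomach. Of the 20 goblet cell genes, Creb3l4 alone passed, and the median was -0.17 (adjusted p = 0.0567); Klk1 was the next by size, higher by at least 0.92, with both means below the filter level without KO 1. Of the 6 genes of antral and neck mucous gland cells, none passed over all genes, and Dmbt1, a secreted mucosal scavenger receptor, passed when adjusted over the list alone, at 2.21 (SE 0.61); Cxcl17 was at 0.74. The surface mucous list of 11 genes had a median of 0.02, with Muc1 at -0.31, the 15 genes of mucin-type O-glycan synthesis had a median of 0.01, with St6galnac6 lower by at least 0.14 (both means below the filter level without WT 1) and Fut2 at -0.42, and the 40 genes of the ER secretory machinery had a median of 0.07, with Creb3l4 alone past the threshold and Ern2 at -0.89. The medians of parietal (9 genes), chief (6 genes) and enteroendocrine (16 genes) cells were -0.11, -0.01 and -0.15. Gcg, the glucagon precursor, passed when adjusted over the enteroendocrine list alone, at -0.80. So did the antibody joining chain gene Jchain in the list of B and plasma cells, higher by at least 1.19 (0.60 without KO 2), a gene named after its value was seen. The other 4 genes of that list were negative, and its median was -1.51 (-0.16 with dim means at the filter level). The median and the mean differed in sign for the ER, O-glycan and stem cell lists, and the remaining lists did not pass.

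In HET stomach no gene was past the threshold against WT in limma, with 173 genes at an unadjusted p under 0.05, and no list passed. Between KO and HET stomach, Creb3l4 was again the only gene past the threshold, at -3.02 (SE 0.32, adjusted p = 0.0366), at least 4.03-fold lower in KO; it lost its call in 14 of 22 alternatives (adjusted p from 0.00146 to 0.446), and without HET 2 the count was 18. Of the lists, 6 passed between KO and HET. The squamous list (median -3.18, and -2.43 with dim means at the filter level), the goblet list (-0.25), the defence list (-0.89, and -0.10) and the B and plasma cell list (-0.90, with the means of 3 of its 5 genes below that level in both groups) were lower, and the lists of proliferation (0.12) and of immediate-early genes (0.31) were higher. None held with an estimated correlation (smallest adjusted p = 0.266 with an estimated correlation). The squamous list differed by 3.70 between the 2 HET arrays alone, and its median was -1.28 without HET 1 and -5.08 without HET 2, where it passed with an estimated correlation too (adjusted p = 0.0153). The proliferation call was lost without HET 2 (adjusted p = 0.284), KO 1 (0.728) or WT 2 (0.0586). The immediate-early call was lost without HET 2 (0.693), KO 1 (0.0528) or KO 2 (0.401), and the calls of the defence (0.0844) and B and plasma cell lists (0.428) without KO 1.

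The same comparison in colon found 2 genes higher and 2 lower in KO. The acute-phase serum amyloid genes Saa1 and Saa2 lay below the 40th percentile in both WT arrays and at 13.14 ± 0.19 and 13.21 ± 0.19 (SD, n = 2) in the KO arrays. Saa1 was at least 97.8-fold and Saa2 at least 102.3-fold higher than in WT (adjusted p = 0.000492 for both). They are close paralogues whose probe sets may read one another, and a second Saa2 probe set showed 3.50. With an offset of 1 both calls were lost (adjusted p = 0.0973, and from 1.7e-06 to 0.0973 over the alternatives). Cgref1, a secreted protein with EF hands, fell by 2.11 (SE 0.18, adjusted p = 0.00226), from 11.33 ± 0.15 to 9.22 ± 0.26, in both of its probe sets. Creb3l4 fell by 2.49 (SE 0.32, adjusted p = 0.0463), at least 4.24-fold, with both KO arrays below the 40th percentile. The genes with the next smallest p-values did not pass and were Optc (lower by at least 1.40), the magnesium transporter Slc41a2 (at least 2.33), the matrix protein Fbln1 (-1.08), Homer2 (1.81), Itih5 (1.04) and the centromere histone Cenpa (1.05), with adjusted p-values from 0.0609 to 0.25. A second Fbln1 probe set showed only -0.30. There were 886 genes with an unadjusted p under 0.05 against 396 by chance. In the same fit the number was 761 for HET against WT and 325 for KO against HET. The excess over all arrays was therefore found only against the WT arrays and cannot be assigned to loss of Spdef. Creb3l4 was lower in KO in each of 22 alternatives and lost its call in 18 of them (adjusted p from 0.00204 to 0.783), while Cgref1, Saa1 and Saa2 lost theirs in 2 each.

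The count in colon depended on single arrays, WT and KO. It was 24 without colon WT 2 and 963 without colon WT 1, where the array labelled colon WT 2 was the only WT array left, and it was 34 without colon KO 1. Without colon WT 2, a comparison that rests on 1 WT array whose spread is taken to be that of the other groups, 3 genes were higher and 21 lower in KO. These, chosen after their values were seen, included Spdef itself at -1.80, Rap1gap (-3.02), a regulator of the small GTPase Rap1, Mt3 (lower by at least 2.15), Creb3l4 (at least 2.58), Tpd52l1 (at least 1.82), the calcium-binding protein Tesc (at least 2.12), Cgref1 (-2.01), Slc41a2 (at least 1.79), Hgfac (-1.77), Gfpt1 (-1.52), which starts the hexosamine pathway that feeds glycan synthesis, Elapor1 (-1.41) and the chemokine Ccl9 (-1.29). Their adjusted p-values ran from 0.00205 to 0.0373.

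Of the 23 lists tested in colon, 3 passed. Proliferation genes were higher in KO, positive in 22 of 24 genes with a median of 0.52 (adjusted p = 5.9e-05), with Bub1 at 1.09, Mki67 at 0.93, Ccnb2 at 0.89 and Birc5 at 0.76. None passed over all genes and 5 passed when adjusted over the list alone. The list's mean level was 8.41 in colon KO 1 and 9.08 in colon KO 2, against 8.18 to 8.29 in the other colon arrays, and without KO 2 the list had a median of 0.21 and lost its call (adjusted p = 0.544). Lists of other cell types were also high in KO 2, with a mean of 9.34 for B and plasma cells (7.24 to 8.44 in the other colon arrays) and of 9.49 for exocrine pancreas (6.35 to 8.16). The 7 small intestine genes were lower, with a median of -2.56 (adjusted p = 6.4e-05) (-1.82 with dim means at the filter level), Apoa1 lower by at least 4.13, Apoc3 at -2.86, Rbp2 at -2.64 and Fabp1 lower by at least 1.82, and 2 passed when adjusted over the list alone; these genes were high in the array labelled colon WT 2, and without it the list had a median of -0.31 (adjusted p = 0.202), with Apoa1 lower by at least 0.47, Apoc3 at -0.31, Rbp2 at -1.26 and both means of Fabp1 below the filter level. The 4 adipose genes were lower, with a median of -1.97 (adjusted p = 6.4e-05), Retn lower by at least 1.77, Adipoq at -2.36, Fabp4 at -1.59 and Plin4 at -1.01, and 3 passed when adjusted over the list alone. Their mean level was 9.50 in colon KO 1 and 7.37 in colon KO 2, and the median was -0.65 without KO 2 (adjusted p = 0.00244) and -2.83 without KO 1. None of these calls held with an estimated correlation (adjusted p = 0.874 with an estimated correlation for each, and 0.122 or more without any 1 colon array).

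The secretory lists did not pass in colon over all arrays. The goblet list of 28 genes had a median of -0.13 (adjusted p = 0.407) with a mean of 0.02, and held Creb3l4 as the only gene past the threshold, with Retnlb, a goblet cell resistin-like protein, at 1.79 (SE 2.03), and at -2.09 without colon WT 2 and -0.14 without colon KO 2. The O-glycan list of 20 genes had a median of 0.07 against a test direction of lower, with St6galnac6 at 2.40, which was 0.01 without colon WT 2 and 4.80 without colon WT 1, and St6galnac1 lower by at least 1.40 (0.80 without colon WT 2), the latter past the threshold when adjusted over the list alone. The ER list of 40 genes had a median of -0.07, with 1 gene past the threshold, Creb3l4, and with Sel1l also past it over the list alone, at -0.83. Of the 16 enteroendocrine genes, 14 had negative differences with a median of -0.21 (adjusted p = 0.0860), Nts at -2.98 (-0.61 without colon KO 2 and -5.35 without colon KO 1) and Slc18a1 at -0.69 (0.03 without colon KO 2). Without colon WT 2, 9 lists passed. The smooth muscle list (median -0.55, adjusted p = 4.4e-06), the goblet list (median -0.46, adjusted p = 4.5e-05), and the fibroblast and matrix (-0.33), O-glycan (-0.44), adipose (-1.77), enteroendocrine (-0.61) and ER lists (-0.07) were lower, and the proliferation (0.48) and myeloid lists (0.34) were higher, with adjusted p up to 0.0488. None of these held with an estimated correlation (adjusted p from 0.309 to 0.839 with an estimated correlation). Without colon KO 2 and with both WT arrays, the goblet list was lower too (median -0.41, adjusted p = 0.000641, and 0.989 with an estimated correlation), and so was the ER list (-0.42), while without colon KO 1 the medians were 0.34 for goblet, not past the threshold, and 0.45 for ER, past it as higher (adjusted p = 5.4e-05, and 0.452 with an estimated correlation). The enteroendocrine list passed as lower without colon KO 1 as well (adjusted p = 4.2e-06, and 0.270 with an estimated correlation).

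**Figure D2:**
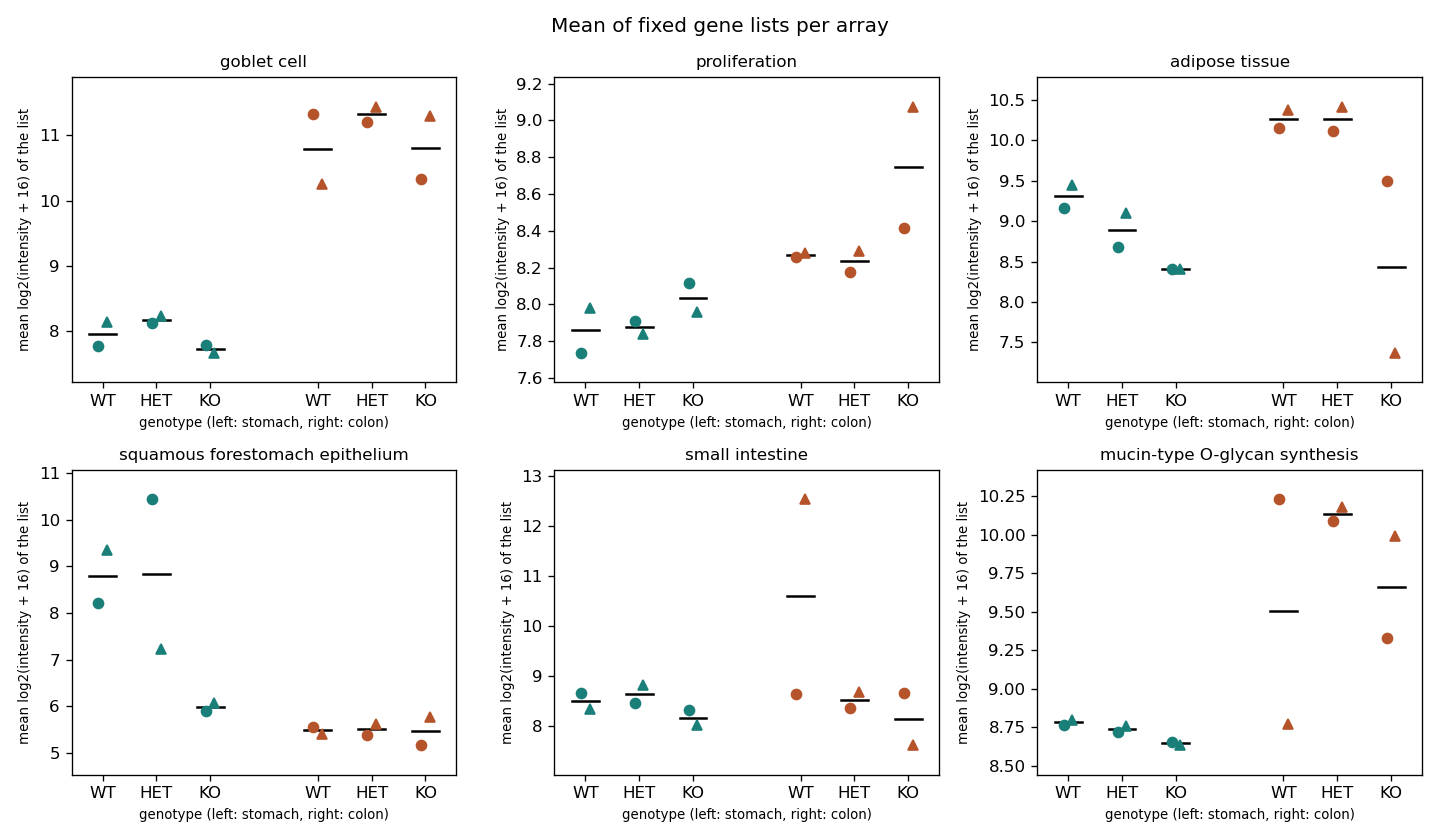
Mean log2(intensity + 16) of 6 gene lists in each array, by genotype within stomach (teal) and colon (orange), over the genes that passed the filter in either tissue. Circles are replicate 1, triangles replicate 2 and bars the mean of the 2 arrays. The squamous list lies at 5.90 and 6.07 in stomach KO, and the goblet list at 11.33 in colon WT 1 against 10.25 in the array labelled colon WT 2.

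In HET colon the serum amyloid genes lay at 12.85 ± 0.04 for Saa1 and 12.86 ± 0.06 for Saa2 (SD, n = 2), and their difference from KO was not past the threshold. Saa1 was at least 79.7-fold and Saa2 at least 80.2-fold higher than in WT (adjusted p = 0.000722 for both), and they were the only 2 genes past the threshold. Without colon WT 2 the count was 6, with Anxa11 (-1.91), Jund (-1.68), Rad23b (-1.61) and Man1b1 (-1.61) lower, and without colon WT 1 it was 1068. Of the lists, the goblet (median 0.43), O-glycan (0.49) and enteric neuron lists (0.83) were higher in HET and the small intestine list (-2.11, and -1.82 with dim means at the filter level) was lower, and none held with an estimated correlation (smallest adjusted p = 0.972 with an estimated correlation). All 4 calls were lost without colon WT 2, with medians of -0.12 for goblet, -0.17 for O-glycan, 0.41 for enteric neuron and 0.12 for small intestine (adjusted p = 0.716, 0.716, 0.358 and 0.716). The smooth muscle (-0.35) and fibroblast and matrix lists (-0.25) were then lower in HET (adjusted p = 0.0392 and 0.00772, and 0.574 for each with an estimated correlation). Without colon HET 2 only the small intestine list passed (median -2.04, adjusted p = 0.00514, and 0.920 with an estimated correlation), and without colon WT 1 the medians were 0.99 for O-glycan, 1.55 for enteric neuron and -3.15 for small intestine.

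The comparison of KO with HET colon uses no WT array for its fold changes. Creb3l4 was lower in KO at -3.03 (SE 0.32, adjusted p = 0.0179), at least 6.18-fold, and Cgref1 at -1.95 (SE 0.18, adjusted p = 0.0136). They were the only 2 genes past the threshold, and both calls were lost with the replicate number as a block (adjusted p = 0.0697), with colon fitted alone and without either HET array, with adjusted p from 0.000925 to 0.918 over the alternatives for Creb3l4 and from 0.00231 to 0.803 for Cgref1. Without colon KO 1 the count was 27. Without colon WT 2, which enters through the normalization and the shared estimate of the spread, 8 genes, named after their values were seen, were lower and none higher. These were Creb3l4, Rap1gap (-2.79), Tesc (lower by at least 2.15), Tpd52l1 (at least 1.59), Cgref1, Slc41a2 (at least 1.66), the monocarboxylate transporter Slc16a7 (-1.50) and Hgfac (-1.35).

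Over all arrays, 10 lists passed between KO and HET colon. The goblet list was lower, with 24 of 28 genes negative and a median of -0.35 (adjusted p = 3.0e-06), as were the O-glycan list with 19 of 20 negative (median -0.36), the enteroendocrine list with 15 of 16 negative (median -0.85), the enteric neuron list with all 7 negative (-0.82), the adipose (-1.95), smooth muscle (-0.24), ER (-0.10) and immediate-early (-0.33) lists. Proliferation was higher, with 23 of 24 genes positive and a median of 0.58 (adjusted p = 2.1e-11), and so was the myeloid list with all 11 positive (0.21). None of the 10 held with an estimated correlation (smallest adjusted p = 0.463 with an estimated correlation). The colon KO arrays differed from each other. Means in KO 1 and KO 2 were 10.33 and 11.29 for goblet, 8.41 and 9.08 for proliferation, 8.35 and 7.41 for enteroendocrine, 8.40 and 7.50 for enteric neuron and 9.50 and 7.37 for adipose genes. Without KO 2 the calls of the enteroendocrine (median -0.14, adjusted p = 0.117), enteric neuron (-0.36, adjusted p = 0.0671) and myeloid lists (0.13, adjusted p = 0.680) were lost, and the proliferation median was 0.26 (adjusted p = 0.0262). Without KO 1 those of the goblet (-0.04, adjusted p = 0.668), O-glycan (-0.12), smooth muscle (-0.10) and immediate-early lists (-0.20) were lost, and the ER list was higher (0.31) instead of lower. Without HET 2 the smooth muscle, ER, immediate-early and myeloid calls were lost (adjusted p from 0.185 to 0.966). The smallest adjusted p with an estimated correlation was 0.0767 over these leave-outs.

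The last comparisons set the tissues and the genotypes against each other. The KO minus WT difference was unlike between stomach and colon for Saa1 and Saa2 (limma adjusted p = 0.00474 for both) and for no other of 8393 genes. Both were below the filter level in every stomach array and in both colon WT arrays, so no fold is given in stomach, and the difference rests on the rise in colon of at least 6.61 for Saa1 and 6.68 for Saa2. There were 9 such genes without colon WT 2, 6 without stomach HET 2 and 391 without colon WT 1, and both calls were lost without stomach KO 2 (adjusted p = 0.0736), with the replicate block (0.0835), with an offset of 1 (0.522) and without the KO array of each tissue with low Xist (0.499). Their adjusted p ran from 2.7e-05 to 0.522 over the alternatives. The test treats the arrays of the tissues as independent, and the labels do not say whether they share animals. The lists of squamous epithelium (median -2.37) and small intestine (1.41) passed in this comparison and did not hold with an estimated correlation (adjusted p = 0.909 with an estimated correlation for each). Creb3l4 was past the threshold in both tissues. It was the only shared gene, among 1 lower in stomach and 2 lower in colon of 7378 genes tested in both (Fisher's exact test, two-sided, p = 0.000271), and the shared call ended in 18 of 22 alternatives. Fisher's test takes the calls of the tissues as independent. They share 1 estimate of the spread per gene over all arrays, and may share animals, so its p-value overstates the support. Cgref1 was lower in stomach KO too, at -0.76, without passing the threshold, and the difference between the tissues for it was not past the threshold. Across the 7378 genes, which are not independent replicates, the KO minus WT differences of the tissues had a Pearson correlation of 0.186 and a Spearman correlation of 0.16.

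HET and KO differences from the same WT arrays were compared with simulated unchanged groups, because the shared arrays alone make them correlate. In stomach the correlation across genes was 0.491 against 0.499 in the simulation, and the covariance differed by -0.0044. In colon it was 0.778 against 0.50, with a covariance higher by 0.145, and Saa1 and Saa2 were called in both. Shared calls numbered 0 in each of 100 simulations of unchanged groups, which leave out any effect, and 0.00051 are given by independent lists, which leave out the shared WT arrays. Without colon WT 2 the correlation in colon was 0.688 against 0.667, and the covariance was higher by 0.052. The correlation was 0.918 without colon WT 1 and 0.156 in stomach without HET 2.

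The X-linked transcript Xist, which is made from the inactive X chromosome, was between 12.34 and 12.86 in 10 arrays. It was 7.48 in stomach KO 2 and 5.70 in colon KO 2, with KO minus WT at -2.38 in stomach and -3.15 in colon (neither past the threshold). The Y-linked genes Eif2s3y, Kdm5d and Uty were below the filter level in all 12 arrays. Without these 2 KO arrays, with 1 array left per KO group, the KO against WT calls of Saa1, Saa2 and Cgref1 in colon were lost in limma (adjusted p = 0.0568 for each). Their sizes changed little, with Saa1 higher by at least 6.49, Saa2 by at least 6.56 and Cgref1 at -2.30. The calls of Creb3l4 against WT were lost too, at least 2.09 lower in stomach (adjusted p = 0.216) and 2.07 in colon (0.229), as were those between KO and HET of Creb3l4 (0.446 in stomach and 0.398 in colon) and of Cgref1 in colon (0.190). Over all alternatives, the adjusted p of Cgref1 in colon KO against WT ran from 0.000306 to 0.175, and the ranges of the others are given above.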

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

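The tests of the array labelled colon WT 2, the squamous list and chromosome 7 were chosen after those results were seen, while the test between tissues was planned. The KO minus WT difference of Saa1 and Saa2 was unlike between the tissues by the interaction term, with fitted stomach minus colon differences of -8.23 and -9.15. These sizes are no bounds, as every stomach array and both colon WT arrays lay below the filter level, and the values support a rise in colon of at least 6.61 and 6.68. Both calls were lost with the replicate block (adjusted p = 0.0835), with an offset of 1 (0.522), without stomach KO 2 (0.0736) and without the KO array of each tissue with low Xist (0.499), over a range from 2.7e-05 to 0.522. Among probe sets with no gene in the annotation, which the comparisons above did not use, 3 passed between KO and WT in stomach (1 higher, 2 lower of 2525) and 2 in colon (both higher of 2523), with the smallest p in colon at a difference of 3.45.

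The array labelled colon WT 2 stood apart from the other 5 colon arrays. Scaling of the array is argued against by its mean Spearman correlation across genes of 0.88 on the deposited values, against 0.921 to 0.950 for the others, since no scaling changes ranks. Creb3l4 and Cgref1 lay at least 1.95 above the higher colon KO array in this array, but both were called with it counted as WT. They were also lower in KO than in HET colon, where no WT array enters the difference. Spdef went the other way, at 8.74 against 9.08 and 9.25 in the KO arrays. These values do not settle whether this array was exchanged with a colon KO sample. Car1, Aqp8 and Hoxa10 were low in this array, so its label as colon tissue is in doubt. The small intestine list lay 3.78 above the mean of the other arrays, highest in this array for 7 of 7 genes. Small intestine tissue in the sample is therefore a candidate explanation that stays open, as does a sample from outside these groups. Beyond this list, no biological explanation was tested.

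The squamous list was lower in stomach KO. Quantile normalization as the source is argued against by the median of -2.50 on the deposited values, which were themselves already scaled to a common trimmed mean. Between the HET arrays, which share a genotype, all 9 genes differed in 1 direction with a median of 3.70, so a varying amount of forestomach in the dissected samples may account for the pattern. An effect of Spdef loss on squamous cells would also give the KO minus HET median of -3.18, and it cannot be told apart from the dissection because the amount of forestomach per sample is not known.

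Genes that set WT stomach apart from HET and KO stomach at an unadjusted p under 0.001 lay often on chromosome 7. Saa1 and Saa2 lie there too, while Spdef lies on chromosome 17. In the order of genes along chromosome 7, the chosen ones lay between 8.85% and 50.7%, and Saa1 and Saa2 lie at 41.5%. Saa1 and Saa2 were high in both HET and KO colon, so their rise cannot be told apart from this pattern of WT against the rest. Uri1, Pop4, Uevld and Arrdc4, named above for stomach, are among the chosen genes. Of the 23 chosen genes, 10 lay on chromosome 7, against 1.69 expected (permutation p = 1e-05, the smallest that 100000 draws can give). This argues against a difference in handling of the WT arrays as the source of the chromosome 7 share. Handling stays open for the chosen genes on other chromosomes. Of the chromosome 7 genes, 100% of the 9 measured in colon went the same way there, as did 8 of 10 other chosen genes. The agreement between tissues therefore does not set chromosome 7 apart. A strain segment shared by HET and KO animals may account for the chromosome 7 share, though the labels give 1 strain. A graded effect of Spdef copies cannot be told apart, with a median HET to KO step in colon of 0.23 after a WT to HET step of 0.69.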

How the results depend on the processing

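The alternative without the KO array of each tissue with low Xist was chosen after the data were seen; the others were planned. Where leaving out an array left 1 in a group, its spread was taken to be that of the other groups. The cause of a change was not tested unless stated. Signal over background limits Creb3l4, Saa1 and Saa2, whose lower group lay below the filter level, so their fold moves with the offset by construction.

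Stomach KO against WT had 1 gene, and 0 on the deposited values, 0 with offset 64, 7 with each tissue fitted alone, 0 with the replicate block and 0 without the low-Xist arrays. Stomach KO against HET had 1, and 0 on the deposited values, with offset 64, without the intensity trend, with the replicate block and without the low-Xist arrays. Colon KO against WT had 4, and 1 with offset 1, 2 with each tissue fitted alone and 0 without the low-Xist arrays. Colon HET against WT had 2, and 0 with offset 1. Colon KO against HET had 2, and 0 with each tissue fitted alone, with the replicate block and without the low-Xist arrays. The difference between tissues had 2, and 0 with offset 1, with the replicate block and without the low-Xist arrays; it could not be computed with each tissue fitted alone. WT colon against WT stomach had 2293, and 1517 with the replicate block. The shared gene of the tissues was 1, and 0 on the deposited values, with offset 1, with offset 64, without a filter, without the trend, with each tissue fitted alone, with the replicate block and without the low-Xist arrays. Stomach lists past the threshold were 2, and 5 on the deposited values, 4 without a filter, 5 with each tissue fitted alone, 1 with the replicate block, 5 without the low-Xist arrays and 0 with an estimated correlation. Colon lists were 3, and 6 without a filter and 0 with an estimated correlation. Stomach HET against WT had 0 in limma in every alternative, with 173 genes at an unadjusted p under 0.05 as fitted.

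Leaving out each array in turn gave 0 to 9 genes for stomach KO against WT, 0 to 18 for stomach KO against HET, 3 to 963 for colon KO against WT, 2 to 1068 for colon HET against WT, 0 to 27 for colon KO against HET, 0 to 391 for the difference between tissues, 1105 to 2943 between the WT tissues, 0 to 2 shared genes, 1 to 5 stomach lists and 3 to 9 colon lists. The HET and KO correlation ran from 0.156 to 0.647 in stomach and from 0.611 to 0.918 in colon. Spdef ran from -0.44 to -0.21 in stomach and from -1.80 to 0.42 in colon.

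For 118 differences of named genes, 2400 of 2543 values kept their direction and side of the threshold, 77 lost a call, 48 gained one and 18 changed sign. Single genes changed sign in some of these, without passing the threshold where the sign changed. In colon, the ranges were -0.35 to 7.01 for Car1, -0.14 to 0.85 for Glipr1, -0.25 to 2.61 for Ms4a1, -1.41 to 0.028 for Slc18a1, -2.09 to 5.69 for Retnlb (-0.14 without KO 2), -0.11 to 4.75 for Aqp4, -6.73 to 0.43 for Xist and -0.71 to 1.72 for Synpo2. In stomach they were -1.0 to 0.021 for Krt20, -2.53 to 0.69 for Amy2a5 and -5.02 to 0.26 for Xist. Without the low-Xist arrays, values were -0.14 for Glipr1, 0.027 for Slc18a1, -0.13 for Retnlb and 0.43 for Xist in colon, and 0.69 for Amy2a5 and 0.26 for Xist in stomach.

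With the replicate block, colon KO against WT had 3 genes (2 higher, 1 lower). Deviations of arrays with the same number had correlations across genes from -0.37 to 0.31 between genotypes within a tissue. As their signs differed, no steady pairing by number was seen within a tissue. With 2 arrays per group, a pairing of some arrays stays open. Over the tissues, arrays with the same genotype and number had correlations from 0.0627 to 0.122, and Xist was low in KO 2 of both, so pairing by animal over the tissues stays open.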

Other observations

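The tests on Xist in this part were chosen after its values were seen, as was keeping the tissues together in the splits of the arrays, while drawing splits within each tissue was planned. Transcripts made mainly by liver were present in stomach at uneven levels. Alb lay at 12.42 and 9.36 in WT, 8.39 and 11.66 in HET and 7.26 and 6.53 in KO, and Mup3 at 11.16 and 7.81 in WT, 8.63 and 8.57 in HET and 5.61 and 4.36 in KO. For both genes the KO arrays lay below every WT and HET array. Alb, chosen after its values were seen, differed between the arrays of WT and of HET, and Mup3 between those of WT. In colon, the gastric surface gene Ctse was at 1.73 and the pancreatic elastase Cela1 at 2.24 in KO against WT, neither past the threshold over all genes and both past it when adjusted over their list alone. Without colon KO 2 they were at 0.62 and 1.08, and without colon KO 1 at 2.84 and 3.41. The pancreas list had a mean of 6.95 in KO 1 and 9.49 in KO 2, and the B and plasma cell list one of 7.97 and 9.34. The median difference of the pancreas list was 1.73 over all arrays and -0.53 without colon WT 2. Cela1 itself stayed positive in each alternative, from 1.07 to 3.41. The monocyte receptor gene Cd14 was at 1.15 (0.45 without colon KO 2) and the interferon-induced Ifit1 at -1.51 (-0.28 without colon KO 2), neither past either threshold.

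Low Xist in KO replicate 2 of both tissues may come from an animal with a single X chromosome, male or not, or with loss of Xist. The highest Y-linked value in these arrays was 6.01, below the filter level. No array shows that these probe sets work, so this value cannot decide whether the animal was male. Genes that escape X inactivation had a median of -0.26 in these arrays against the others of their tissue, with 6 of 8 values below 0. A single X would lower these genes in a male as well, so the values, from 4 genes, do not tell a male from a female.

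Over both tissues, KO was set against WT and HET together. Creb3l4 was the only gene of 8393 past the threshold (limma adjusted p = 3.0e-05), lower in KO by at least 2.21, as all 4 KO arrays lay below the filter level. The fit treats the arrays of the tissues as independent. The labels do not say whether arrays of the 2 tissues with the same number came from 1 animal. If they did, the arrays make 15 splits that keep the tissues together, too few for a share under 0.05. Of these, 2 gave as many genes, the real one with 1 gene and the split of WT from HET and KO, the highest of the others, with 5 (Arrdc4, Nup62, Uri1, Pop4 and Optc), which points to a structure that sets the WT arrays apart. Splits drawn separately within each tissue, which count only if the tissues came from separate animals, gave as many genes in 1 of 100 drawn from 225, the real one, and 0 in the highest of the others drawn; the draw did not include the split of WT from HET and KO, which is 1 of the 225 and gives more genes than the real one.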
